A study of Mus musculus with 115 samples.

How the data were processed

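The deposited tables hold raw read counts per amplicon, made by the authors from AmpliSeq mouse transcriptome libraries run on Ion Torrent instruments with genome build mm10, per the labels. The aligner, the counting software and any filters are not given in the sources used here. Each of 14 tables holds 8 barcodes, which gave 112 bulk libraries and 23930 amplicons, each with a gene symbol. Symbols that a spreadsheet had turned into dates were restored for 27 amplicons. The series lists 115 samples, and the 3 single-nucleus samples were not analysed here.

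The replicate was the heart. Libraries sharing title number, genotype and title code were read as repeat libraries of 1 heart and their counts summed. Reading the number as the heart is an interpretation, since the labels do not explain it. Libraries 80a and 80b, whose labels name another vector than their title code, were assigned to no group. Hearts 61 and 91 formed a group of their own for the same reason. The 7 groups entered 1 fit in edgeR 4.0.16 (R 4.3.3) without other covariates, with genes filtered by filterByExpr, TMM scaling and the quasi-likelihood F-test, which left 15403 genes tested. P values were adjusted over all tested genes by the Benjamini-Hochberg method, with 0.05 as the threshold. CPM values use TMM-scaled totals, and log2 values a prior count of 2. The interactions are differences of log2 changes between vectors in the same fit. TMM factors lay between 0.959 and 1.058.

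Gene lists were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01. Of 38 lists fixed in advance, 36 had the 3 or more tested members required, and their p values were adjusted within each comparison. Counts of list members use adjusted p over all tested genes, with counts adjusted over the list alone beside them. "Did not overlap" means that all hearts of 1 group lay above all hearts of the other, and the chance share is that of random ranks.

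Genes were named by a rule: in each pairwise comparison the 8 largest rises and the 8 largest falls past the threshold with at least 5 CPM in the higher group and no overlap, in the interactions the 5 largest on each side, in all comparisons Slc25a4, Slc25a5, Nppa, Nppb, Myh7, Fgf21 and Gdf15, and up to 4 members of each list with the smallest adjusted p. The text gives part of the genes the rule allows. A group in which 1 to 3 reads remained was not given as a fold.

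The groups, the tests, the gene lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were other size factors, no low-count filter, DESeq2 1.42.0, each library as a replicate, libraries a and b only, each heart left out, the hearts whose libraries sit in other tables than most of their group left out, hearts 61 and 91 placed in either vector group, libraries 80a and 80b added to heart 80, only the compared groups in the fit, Xist as a covariate and, for the lists, an estimated correlation, a prior count of 0.5 and fry. Another alternative fitted single libraries in limma voom with the library table as a covariate and a within-heart correlation of 0.197, where the contrast could be estimated. That fit links groups through hearts in the same tables. At its low within-heart correlation repeat libraries count largely as separate units, so its p values can be too small and its gene counts too high. Control vector wild type hearts shared tables only with knockout heart 35, knockout ND6 heart 22 and hearts 61 and 91. Knockout hearts 36 and 38 shared theirs with knockout ND6 hearts 20 and 21. Ant1 vector wild type hearts shared tables only with knockout heart 20, and with no knockout ND6 heart. The other Ant1 vector knockout hearts shared theirs with the knockout ND6 hearts. Added later were fits without hearts 27 and 37, without library 27a, without hearts 5 and 8, and without chromosome 8 from 30 to 95 Mb.

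Noise between pairs of libraries was checked on amplicons averaging at least 100 counts, as the median squared difference relative to counting noise alone. Its median over pairs was 5.03 between hearts of a group, and between libraries of 1 heart 2.38 in the same table and 3.23 in different tables. Some pairs in different tables lay closer than pairs in the same table, such as 1.35 for 83a and 83c against 2.08 for 83a and 83b. The medians within hearts are thus no measure of a table effect. Hearts 27 and 37, left out of these medians for single hearts, had 5.52 within a table and 26.7 between tables. The test was tried on simulated data with 200 genes changed at known folds. Over 7 comparisons 83.3% to 93.8% were recovered at 4-fold, 59.1% to 85.1% at 2-fold and 34.8% to 50.7% at 1.5-fold, with 5 to 11 false calls among 15095 to 15125 genes tested. These counts were drawn without differences between library tables, so false calls that come from such differences could not appear. In the simulated list test the moved list passed and 0 of 30 unmoved lists did. Its genes were drawn independently, so it cannot show false list calls that come from correlation between genes. Amplicon positions were taken from a mouse gene table (GRCm38.p6), by symbol for 21913 amplicons and by synonym for 741, with 1276 left unplaced. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.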

Results

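RNA from mouse hearts was counted on an amplicon panel of 23930 targets, each assigned to a gene, in 14 tables of 8 libraries. The mice were wild type (C57BL/6JEiJ), lacked Ant1 (the knockout hearts), or lacked Ant1 and carried the ND6 P25L change in mitochondrial DNA (the knockout ND6 hearts). Ant1, encoded by Slc25a4, is the heart's main carrier of ADP and ATP across the inner mitochondrial membrane, and ND6 is a subunit of respiratory complex I. The mice had been given 2.5e+11 vector genomes of an adeno-associated virus in the pericardium, carrying either Gfp with mouse Ant1 (the Ant1 vector) or Gfp alone (the control vector). The number in each title was read as the heart, which gave 22 hearts. The control vector hearts were 4 wild type (22 libraries), 3 knockout (18 libraries) and 3 knockout ND6 (16 libraries). The Ant1 vector hearts were 3 wild type (10 libraries), 4 knockout (20 libraries) and 3 knockout ND6 (16 libraries). Another 2 knockout ND6 hearts, 61 and 91 (8 libraries), were labelled control vector under the title code of the Ant1 vector hearts and formed a group of their own.

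Library totals ran from 2893780 to 8531273 counts, with a median of 6591301.5, and totals per heart from 16827518 to 54779297 counts. The series gives 1, 3, 6, 9 and 12 months after injection, but the labels give no heart its age, so age enters no comparison. The panel held no amplicon for Slc25a5, Myh7 or any mitochondrially encoded gene, ND6 included. Fgf21 fell under the count filter in all comparisons. Intervals and floors from counts cover counting error only.

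Slc25a4 was read first, as a check of Ant1 loss in each heart and, in hearts without Ant1, of the vector. It shows neither the ND6 change nor the vector of a wild type heart. Wild type hearts with the control vector held 10392 ± 1347 CPM (SD, n = 4) of Slc25a4 transcript (chromosome 8, 46207168 to 46211062, mm10), and wild type hearts with the Ant1 vector 9812 ± 731 CPM (SD, n = 3). Knockout hearts with the control vector held 2.03 CPM (heart 35, 62 counts), 0.617 CPM (heart 36, 19 counts) and 0.331 CPM (heart 38, 10 counts). Knockout ND6 hearts with the control vector held 0.363 CPM (heart 20), 0.219 CPM (heart 21) and 0.851 CPM (heart 22). Knockout hearts with the Ant1 vector held 202.7 ± 28.0 CPM (SD, n = 4), and each lay between 1.68% and 2.32% of the wild type control vector mean. Knockout ND6 hearts labelled Ant1 vector held 55.6 CPM (heart 37, 0.535% of that mean) and 66.7 CPM (heart 5, 0.642%). The heart labelled 8 in that group held 0.732 CPM from 20 counts, inside the range of the control vector knockout ND6 hearts. Hearts 61 and 91, labelled control vector, held 169.1 and 151.3 CPM (1.63% and 1.46%), more than any knockout ND6 heart labelled Ant1 vector. The single libraries of knockout heart 27 spread from 72.1 to 270.2 CPM. Where the amplicon lies relative to the deleted part of Slc25a4 is not given in the sources used here.

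**Figure D1:**
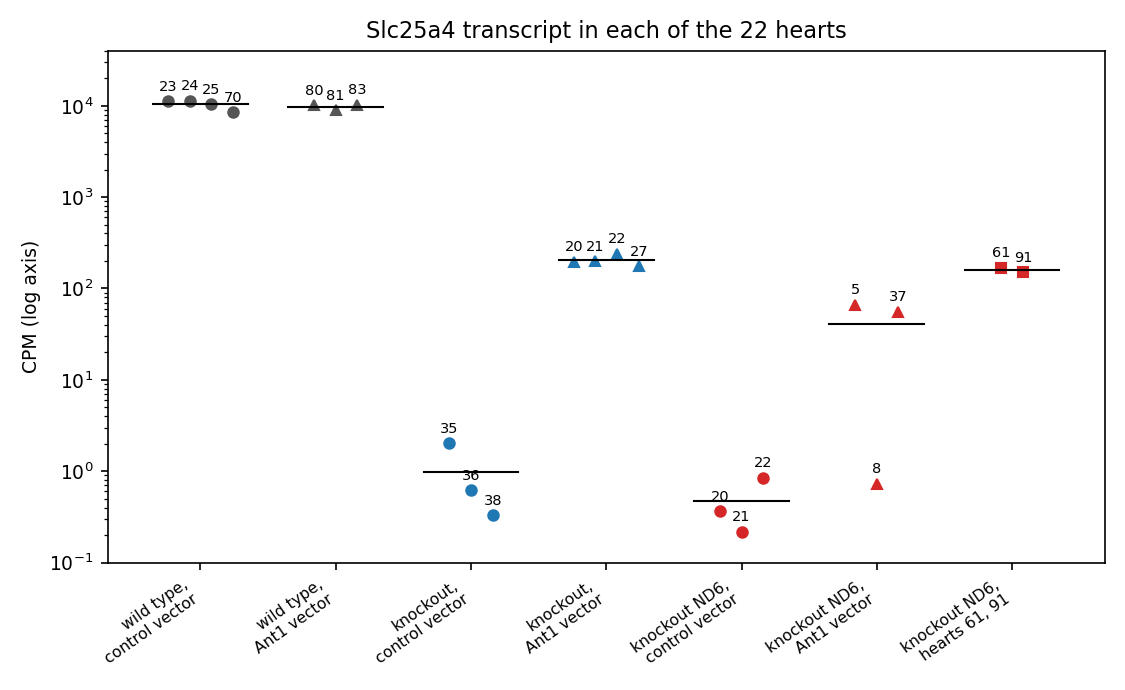
Slc25a4 transcript in CPM (log axis) in each of the 22 hearts, by genotype and labelled vector, with heart numbers beside the points and a line at each group's mean. The heart labelled 8 lies at 0.732 CPM, and hearts 61 and 91 at 169.1 and 151.3 CPM.

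The first comparison asked what loss of Ant1 changed under the control vector (3 knockout against 4 wild type hearts). Acta1, the skeletal alpha-actin that strained adult heart muscle expresses again, rose 6.25-fold, from 139.9 ± 37.4 CPM (SD, n = 4) to 874.4 ± 174.8 CPM (SD, n = 3; adjusted p = 3.1e-06). Nppb, the natriuretic peptide of the loaded ventricle, rose 2.66-fold, from 485.4 ± 149.2 CPM (SD, n = 4) to 1290.3 ± 290.3 CPM (SD, n = 3; adjusted p = 0.00106). Ankrd1, a stress-responsive protein of the sarcomere and nucleus, rose 2.08-fold (adjusted p = 0.000193), and the small heat shock genes Hspb7 and Cryab rose 1.53-fold (adjusted p = 3.48e-05) and 1.49-fold (adjusted p = 0.000157). For each of these genes all 3 knockout hearts lay above all 4 wild type hearts. Nppa, the atrial natriuretic peptide, did not pass the test (1.01-fold, adjusted p = 0.986), and neither did Gdf15, a secreted marker of mitochondrial stress, at 5.53 ± 0.495 CPM (SD, n = 3) against 4.12 ± 1.8 CPM (SD, n = 4; adjusted p = 0.601).

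Part of the genes of mitochondrial protein synthesis rose with Ant1 loss. Of 69 mitochondrial ribosomal protein genes 24 rose and none fell (31 adjusted over the list alone), with a list adjusted p = 5.72e-12, and adjusted p = 0.337 with an estimated correlation. Mrps23 went from 363 ± 35.3 CPM (SD, n = 4) to 589.6 ± 24.6 CPM (SD, n = 3; adjusted p = 2.11e-05), and Mrpl43 and Mrps18b rose 1.52-fold and 1.48-fold. Of 19 genes of the TCA cycle and pyruvate oxidation 7 rose (9 adjusted over the list alone; list adjusted p = 0.00431, and adjusted p = 0.39 with an estimated correlation), among them Pdhx (1.70-fold), Pdhb (1.32-fold) and Ogdh (1.28-fold). Of 11 genes of mitochondrial fusion and fission 4 rose (7 adjusted over the list alone; list adjusted p = 0.00171, and adjusted p = 0.116 with an estimated correlation), including Mief2 (1.56-fold) and Opa1 (1.23-fold). Polrmt, the mitochondrial RNA polymerase, rose 1.56-fold and the nuclear receptor gene Esrrg 1.35-fold, 2 of the 4 of 17 biogenesis genes past the threshold (5 adjusted over the list alone; list adjusted p = 0.0198, and adjusted p = 0.39 with an estimated correlation). That list passed neither without knockout heart 38 (adjusted p = 0.0573) nor without wild type heart 70 (adjusted p = 0.0977). Among complex I subunits 3 of 31 rose (1 adjusted over the list alone), Ndufb7 by 1.34-fold, and the list's adjusted p of 0.00276 became 0.128 without wild type heart 70 and 0.762 with an estimated correlation. With the sex marker Xist as a covariate Ogdh, Polrmt and Opa1 no longer passed (adjusted p = 0.0528, 0.0616 and 0.123). The Y-linked gene Ddx3y stood at 238.1 ± 6.6 CPM (SD, n = 4) in wild type and 251 ± 9.01 CPM (SD, n = 3) in knockout hearts. These hearts thus showed no sex difference that Xist could correct, and the lost calls are no sign of one. Over all their alternatives the adjusted p ran from 8.72e-08 to 0.123 for Opa1, from 1.73e-09 to 0.0616 for Polrmt and from 5.56e-06 to 0.0528 for Ogdh.

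Fibroblast markers fell with Ant1 loss, and single named genes of glycolysis and mitophagy changed in either direction. Hk1, which commits glucose to glycolysis, rose 1.51-fold while Ldha, which makes lactate, fell 1.62-fold (adjusted p = 7.54e-05 and 5.2e-05). The mitophagy receptor gene Optn rose 2.02-fold and the mitophagy kinase gene Pink1 fell 1.45-fold (adjusted p = 8.57e-05 and 5.85e-05). Mtor rose 1.74-fold, the calcium handling gene S100a1 1.62-fold and Ckmt2, the mitochondrial creatine kinase of muscle, 1.44-fold. Of 8 fibroblast marker genes 6 fell (6 adjusted over the list alone; list adjusted p = 4.33e-05, and adjusted p = 0.0177 with an estimated correlation), led by Gsn, which went from 1045.8 ± 63.0 CPM (SD, n = 4) to 628 ± 58.4 CPM (SD, n = 3; adjusted p = 5.7e-07). Dpt fell 1.57-fold and Vim 1.39-fold. Of 24 interferon response genes 4 fell (5 adjusted over the list alone; list adjusted p = 0.00431, and adjusted p = 0.414 with an estimated correlation), with Irf9 down 1.36-fold (adjusted p = 0.0116, and 0.0783 without knockout heart 36). The list of fetal and stress genes of heart muscle had 8 higher and 2 lower of 19 (10 and 2 adjusted over the list alone), with a list adjusted p of 0.0127, of 0.0573 without knockout heart 38, and of 0.488 with an estimated correlation. Across comparisons 3 list calls held with an estimated correlation: fibroblast markers here and in the knockout ND6 hearts against wild type, and the cell cycle in knockout ND6 against knockout hearts.

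Some of the widest differences between knockout and wild type hearts were in genes of chromosome 8, which also carries Slc25a4. Calr, the calcium-binding chaperone of the endoplasmic reticulum (chromosome 8, 84842088 to 84846931), went from 516 ± 29.1 CPM (SD, n = 4) to 2.97 ± 0.569 CPM (SD, n = 3; log2 change -7.44, adjusted p = 8.38e-17). Ubxn8, Zswim4 and Ucp1 on the same chromosome had log2 changes of -7.42, -6.76 and -4.99. Of amplicons with at least 5 CPM in wild type control vector hearts, 5 of 535 on chromosome 8 and 4 of 9059 elsewhere were 16-fold or more lower in knockout hearts. In all 4 comparisons of knockout or knockout ND6 with wild type hearts this held for 4 on chromosome 8, among them Calr, Ubxn8 and Zswim4 but not Ucp1, and for 0 elsewhere. The widest rises were in Sycp1, a gene of meiotic chromosome pairing (log2 change 7.78, adjusted p = 3.6e-15), the nitric oxide synthase gene Nos1 (3.97, adjusted p = 7.77e-09), Arhgap9 (3.28, adjusted p = 2.95e-07) and Tmem116 (2.83, adjusted p = 3.63e-12). In all 8 genes the knockout and wild type hearts did not overlap.

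In this comparison 2220 of 15403 genes passed adjusted p 0.05, 1261 higher and 959 lower, and 4388 had an unadjusted p under 0.05. The hearts did not overlap in 2095 of the 2220 and in 4114 of all genes tested, where chance gives 5.71%. Without knockout heart 38, 1366 genes passed. With the library table as a covariate 2726 passed, 1716 of them shared, and the log2 change was 2.76 for Acta1, 1.31 for Nppb, 1.16 for Ankrd1, 0.70 for Gdf15 (adjusted p = 0.192), 0.73 for Mrps23, -0.72 for Gsn and -7.55 for Calr.

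Knockout ND6 hearts were then set against wild type hearts under the control vector (3 against 4 hearts), which asks for the joint effect of both defects. Gdf15 rose 9.72-fold, from 4.12 ± 1.8 CPM (SD, n = 4) to 40.1 ± 10.4 CPM (SD, n = 3; adjusted p = 5.34e-05). The gene lies on chromosome 8 (70629393 to 70632470), between Ubxn8 and Calr. Nppb rose 4.06-fold to 1973 ± 232 CPM (SD, n = 3; adjusted p = 3.6e-05), Acta1 4.54-fold to 635 ± 322 CPM (SD, n = 3; adjusted p = 3.85e-05) and Ankrd1 3.20-fold to 3963 ± 401 CPM (SD, n = 3; adjusted p = 8.88e-07). The sarcomere adaptor gene Fhl2 fell 1.81-fold, from 2066 ± 296 CPM (SD, n = 4) to 1144 ± 48.4 CPM (SD, n = 3; adjusted p = 3.97e-05), and Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell 1.28-fold (adjusted p = 0.00317). The hearts of both groups did not overlap for any of these genes. Nppa did not pass (adjusted p = 0.964).

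Many cell cycle genes rose with both defects. Of 21 on the list 12 rose and 1 fell (15 and 1 adjusted over the list alone; list adjusted p = 8.63e-08, and adjusted p = 0.286 with an estimated correlation). Rrm2, which supplies deoxynucleotides, rose 3.03-fold from 4.01 ± 0.987 CPM (SD, n = 4) to 12.2 ± 2.24 CPM (SD, n = 3; adjusted p = 7.74e-06), the mitotic kinase gene Cdk1 3.01-fold and the replication gene Mcm2 2.43-fold, while the kinetochore gene Cenpf had a log2 change of -3.12 (adjusted p = 1.09e-07). The stress transcription factor gene Ddit3 rose 1.83-fold (adjusted p = 0.00799), but the integrated stress response list went both ways, with 6 higher and 5 lower of 24 (7 and 6 adjusted over the list alone; list adjusted p = 0.924). Mrps23 rose 1.41-fold, 1 of 10 mitochondrial ribosomal genes that rose out of 69 (12 adjusted over the list alone; list adjusted p = 0.000341, and adjusted p = 0.592 with an estimated correlation). Fibroblast markers had 4 of 8 lower (4 adjusted over the list alone; list adjusted p = 0.000341, and adjusted p = 0.0485 with an estimated correlation), with Gsn down 1.43-fold, Dpt 1.53-fold and Vim 1.38-fold. The macrophage complement gene C1qb fell 1.65-fold (adjusted p = 0.0114, and 0.0791 without knockout ND6 heart 22). Optn rose 2.28-fold. Outside these lists the water channel gene Aqp8 rose by a log2 change of 2.75, Cpne4 by 5.11 and the G protein subunit gene Gnb3 by 2.49, and Calr, Ubxn8 and Sycp1 had log2 changes of -7.54, -7.75 and 8.07.

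Here 1954 of 15403 genes passed, 1034 higher and 920 lower, with 4135 at an unadjusted p under 0.05. The groups did not overlap in 1813 of the 1954 and in 4056 of all genes, where chance gives 5.71%. Without knockout ND6 heart 20, 21 or 22 the count was 1226, 1179 or 999. In the fit with the library table as covariate 2444 genes passed, 1375 of them shared, with log2 changes of 3.42 for Gdf15, 1.95 for Nppb, 1.88 for Acta1, 1.91 for Ankrd1 and 1.76 for Rrm2.

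What the ND6 change adds to Ant1 loss was read from 3 knockout ND6 against 3 knockout hearts, both with the control vector. Gdf15 rose 7.25-fold, from 5.53 ± 0.495 CPM (SD, n = 3) to 40.1 ± 10.4 CPM (SD, n = 3; adjusted p = 0.00563). The inducible heat shock gene Hspa1b rose 6.32-fold, from 6.34 ± 3.05 CPM (SD, n = 3) to 40.1 ± 14.8 CPM (SD, n = 3; adjusted p = 0.000967), and its neighbour Hspa1a rose 5.62-fold (adjusted p = 0.00846). Of 21 cell cycle genes 10 rose and none fell (15 adjusted over the list alone; list adjusted p = 1.98e-20, and adjusted p = 0.0189 with an estimated correlation), among them Cdk1 (3.57-fold, adjusted p = 0.00183), Rrm2 (3.47-fold, adjusted p = 0.000183), Cdc20 (2.80-fold, adjusted p = 0.00558) and Mcm2 (2.09-fold, adjusted p = 0.00229). The interferon-induced GTPase gene Gbp4 rose 2.58-fold (adjusted p = 0.00439). Agt, the precursor of angiotensin, fell 4.97-fold to 4.41 ± 0.404 CPM from 21.9 ± 7.87 CPM (SD, n = 3 each; adjusted p = 0.00183), Gadd45b, a growth arrest gene, fell 4.11-fold (adjusted p = 0.00575) and Hk1 fell 1.51-fold (adjusted p = 0.00251). Every one of these genes kept the groups apart, 3 hearts on each side. Nppb was 1.53-fold higher without passing (adjusted p = 0.33), and neither Nppa (adjusted p = 0.985) nor Slc25a4 (log2 change -1.05, adjusted p = 0.765) passed. Hearts 61 and 91, of the same genotype and labelled vector, lay near the knockout hearts in Hspa1b and Rrm2, with means of 6.15 and 3.55 CPM against 6.34 and 3.50 CPM. With both counted as control vector hearts Hspa1b and Rrm2 passed at log2 changes of 2.06 and 1.31 (adjusted p = 0.0359 and 0.0379), and Slc25a4 turned to 6.00 (adjusted p = 0.0496, and 0.0496 to 1 over its alternatives).

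The mitochondrial ribosomal list passed as lower in the list test at the preset correlation (list adjusted p = 2e-05, and adjusted p = 0.62 with an estimated correlation). No member passed the edgeR threshold over all genes, and 5 were lower adjusted over the list alone. Fatty acid genes had 2 lower of 25 (3 adjusted over the list alone; list adjusted p = 0.00188, and adjusted p = 0.607 with an estimated correlation). In total 83 genes passed as higher and 80 as lower, with 2231 at an unadjusted p under 0.05 and 482 past the threshold in DESeq2. No gene that passed had overlapping hearts, and neither had 3890 of all genes, where chance gives 10%. The total fell with any heart left out, to 79 without knockout heart 35, 66 without 36 and 68 without 38, and to 46 without knockout ND6 heart 20, 79 without 21 and 56 without 22. Hspa1a did not pass without knockout heart 35 or knockout ND6 heart 20 (adjusted p from 0.0569 to 0.062), nor with hearts 61 and 91 counted as control vector hearts (0.0514), and over its alternatives its adjusted p ran from 6.2e-17 to 0.062. With the library table as a covariate 1796 genes passed, among them 96.3% of those called without it, with log2 changes of 2.71 for Gdf15, 2.58 for Hspa1b, 1.88 for Rrm2 and -2.36 for Agt, and Nppb passed at 0.65 (adjusted p = 4.62e-05; 4.62e-05 to 0.613 over its alternatives).

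**Figure D2:**
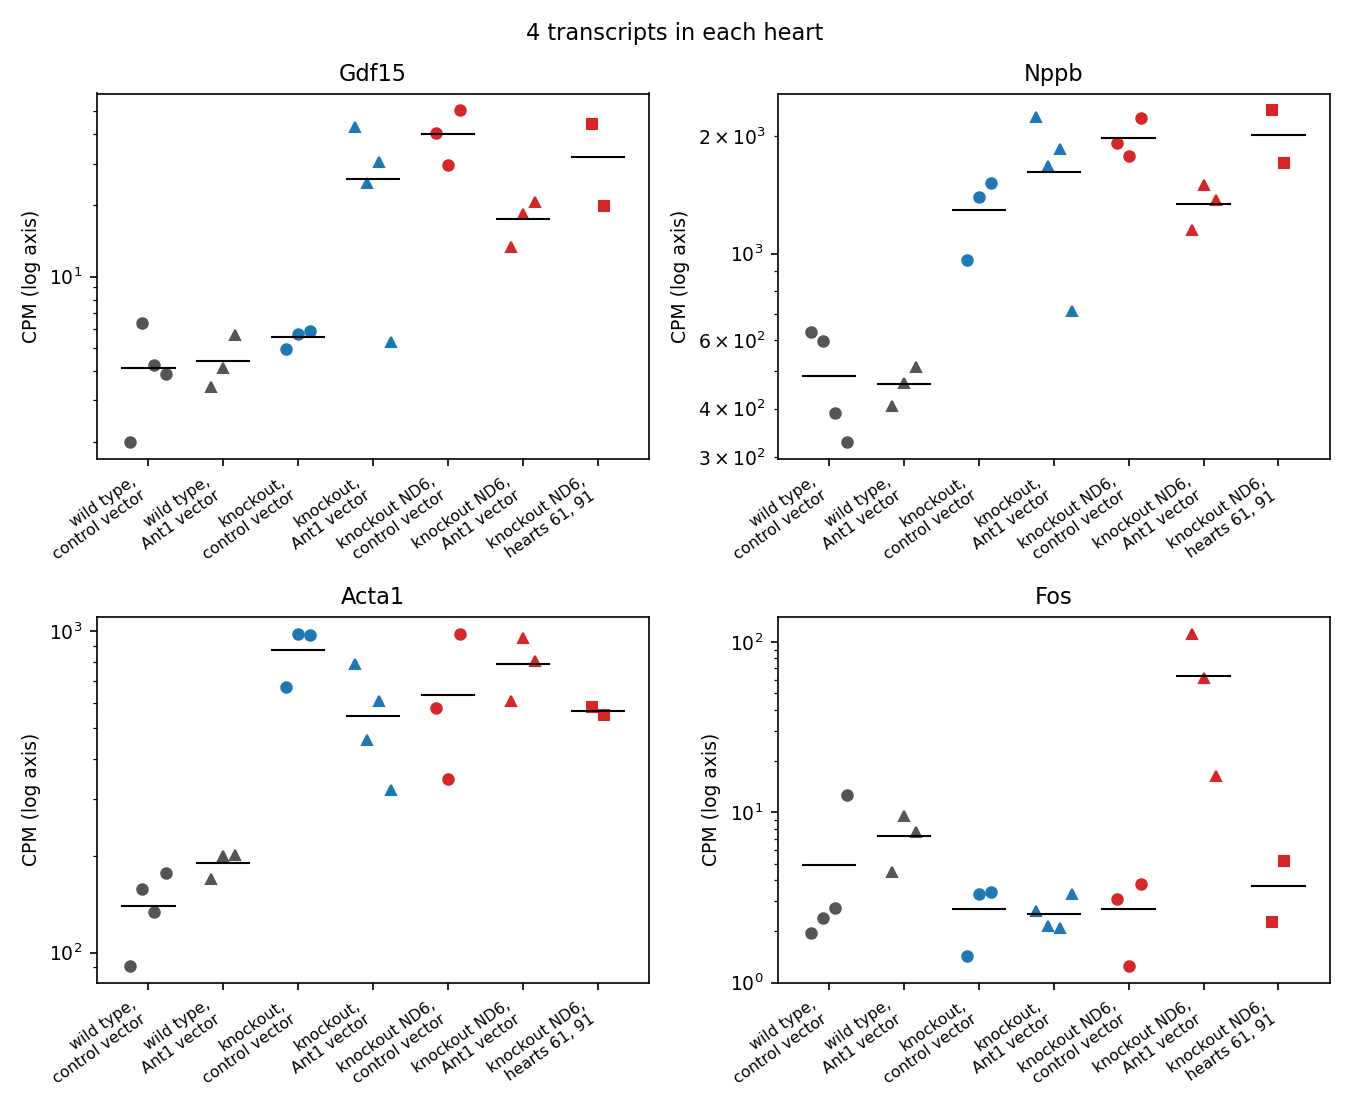
Gdf15, Nppb, Acta1 and Fos in CPM (log axes) in each heart by genotype and labelled vector, with a line at each group's mean. Gdf15 averaged 5.53 CPM in control vector knockout hearts and 40.1 CPM in control vector knockout ND6 hearts, and Fos 63.1 CPM in knockout ND6 hearts labelled Ant1 vector.

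Knockout hearts with the Ant1 vector were set against knockout hearts with the control vector (4 against 3 hearts), to ask what the vector changed in hearts without Ant1. The same 3 control vector hearts were the reference for the ND6 change, so changes found in both comparisons are not independent. Agt, Hk1, Ankrd2, Hspb7 and the mitochondrial ribosomal list were lower and Gdf15 was higher in both. Whether this comes from the shared reference hearts was not tested. Slc25a4 itself rose to 202.7 ± 28.0 CPM (SD, n = 4) from 0.991 ± 0.908 CPM (SD, n = 3; log2 change 7.67, adjusted p = 0.000264). Agt fell 4.01-fold, from 21.9 ± 7.87 CPM (SD, n = 3) to 5.44 ± 0.398 CPM (SD, n = 4; adjusted p = 0.00182), and Hk1 fell 1.48-fold (adjusted p = 0.00182). Myh7b, a slow myosin gene, rose 1.99-fold to 124 ± 18.6 CPM (SD, n = 4; adjusted p = 0.00565). Tcap, which anchors titin at the Z-disc, fell 1.67-fold, Pln, the inhibitor of the calcium pump, 1.61-fold and the stretch-responsive gene Ankrd2 2.51-fold (adjusted p = 0.00592, 0.00899 and 0.00799). Nppb (1.26-fold higher, adjusted p = 0.512) and Nppa (adjusted p = 0.963) did not pass, though Nppb did without hearts 70, 22, 27 and 37 (log2 change 0.58, adjusted p = 0.0411, and 0.0411 to 0.83 over its alternatives).

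Gdf15 did not fall with the Ant1 vector in knockout hearts. It rose 4.64-fold to 25.9 ± 15.7 CPM (SD, n = 4; adjusted p = 0.0119), at 42.9, 24.7 and 30.6 CPM in hearts 20, 21 and 22, while heart 27 lay at 5.29 CPM inside the control vector range. The Gdf15 call was lost without knockout control heart 36 or 38 (adjusted p from 0.0506 to 0.0543) and in a fit of these groups alone (0.0529), against 2.78e-12 to 0.0543 over its alternatives. Mitochondrial ribosomal genes had 10 lower of 69 (15 adjusted over the list alone; list adjusted p = 6.05e-07, and adjusted p = 0.597 with an estimated correlation), with Mrps27 down 1.39-fold. Uqcrc2, a complex III core gene, fell (log2 change -0.59, adjusted p = 0.00831), and so did Dld, a pyruvate dehydrogenase subunit gene, by 1.35-fold (adjusted p = 0.00236), and Hspb7 fell 1.39-fold. Interferon response genes had 4 higher of 24 (12 adjusted over the list alone; list adjusted p = 9.6e-06, and adjusted p = 0.253 with an estimated correlation), with Irf9 up 1.43-fold. Fibroblast markers had 1 higher of 8, Gsn at 1.26-fold (3 adjusted over the list alone; list adjusted p = 0.00338, and adjusted p = 0.162 with an estimated correlation). Endothelial markers had 1 higher of 11, Pecam1 at 1.59-fold (4 adjusted over the list alone; list adjusted p = 0.00938, and adjusted p = 0.253 with an estimated correlation). The elastin gene Eln rose 1.60-fold and Fam13a 1.92-fold. Of these, Mrps27 and Irf9 did not pass without knockout control heart 36 (adjusted p = 0.0889 and 0.0804), Gsn not without 38 (0.0854), and Pecam1 (0.0575 to 0.14) and Eln (0.0624 to 0.0772) not without either. A fit of these groups alone ended the calls of Irf9 (0.0672), Gsn (0.0668) and Mrps27 (0.0696), and libraries a and b alone those of Irf9 (0.0838) and Hspb7 (0.0615), where the adjusted p over all alternatives ran from 3.15e-06 to 0.0838 for Irf9, from 2.24e-14 to 0.0854 for Gsn, from 5.98e-11 to 0.0889 for Mrps27 and from 2e-10 to 0.0615 for Hspb7.

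Between the vectors 842 genes passed in knockout hearts, 338 higher and 504 lower, with 3351 at an unadjusted p under 0.05. For 803 of the 842 the hearts did not overlap, as for 2801 of all genes, where chance gives 5.71%. The count was 489 without Ant1 vector heart 20, 477 without 22, and 415, 222 and 227 without control vector hearts 35, 36 and 38. It was 237 in a fit of these groups alone. Without hearts 70, 22, 27 and 37 it was 1935, with 963 higher and 972 lower, so the excess of lower genes was gone. Among the libraries of the groups compared no table held both vectors in 1 genotype, so in the vector comparisons the vector and the library table cannot be told apart. Libraries 80a and 80b, left out because their vector label differs from their title, shared a table with Ant1 vector wild type libraries.

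The same vector comparison in knockout ND6 hearts (3 against 3) included the heart labelled 8, which lacked Slc25a4, and its directions rest on that label. Slc25a4 rose by a log2 change of 6.42 to 41.0 ± 35.3 CPM (SD, n = 3) from 0.478 ± 0.331 CPM (SD, n = 3; adjusted p = 0.000517), in 2 of 3 hearts. Of 18 immediate early genes, which respond within minutes to stimuli, 14 were higher (15 adjusted over the list alone; list adjusted p = 6.3e-15, and adjusted p = 0.106 with an estimated correlation). Fos rose to 63.1 ± 47.9 CPM (SD, n = 3) from 2.72 ± 1.31 CPM (SD, n = 3; log2 change 4.53, adjusted p = 0.000938), and Egr3, Btg2, Zfp36 and Dusp1 had log2 changes of 3.55, 2.37, 2.08 and 1.87. Fos was 16.3 CPM in heart 37, 111.9 CPM in heart 5 and 61.0 CPM in the heart labelled 8. The clock gene Per1 rose 2.41-fold, from 97.6 ± 11.1 CPM to 235 ± 2.29 CPM (SD, n = 3 each; adjusted p = 0.000882).

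Some endothelial and matrix genes rose in the same hearts, and Hspa1b, Hspa1a and some cell cycle genes fell. Endothelial markers had 4 higher of 11 (5 adjusted over the list alone; list adjusted p = 4.11e-05, and adjusted p = 0.0739 with an estimated correlation), with the junction genes Cldn5 up 4.26-fold, Cdh5 1.45-fold and Esam 1.47-fold. Matrix genes had 3 higher of 32 (6 adjusted over the list alone; list adjusted p = 0.000712, and adjusted p = 0.471 with an estimated correlation), with the fibrillin gene Fbn1 up 2.04-fold (adjusted p = 0.00043). Hspa1b fell 8.21-fold, from 40.1 ± 14.8 CPM to 5.01 ± 2.39 CPM (SD, n = 3 each; adjusted p = 0.000164), and Hspa1a 5.57-fold (adjusted p = 0.00489). Control vector knockout ND6 hearts 20, 21 and 22 held 57.2, 31.4 and 31.8 CPM of Hspa1b. All other hearts, wild type hearts and the heart labelled 8 included, held 2.4 to 14.5 CPM. The fall of Hspa1b here and its rise with the ND6 change thus rest on the same 3 hearts. Cell cycle genes had 3 lower of 21 (8 adjusted over the list alone; list adjusted p = 4.11e-05, and adjusted p = 0.369 with an estimated correlation), with Rrm2 down 3.13-fold, from 12.2 ± 2.24 CPM to 3.92 ± 0.694 CPM (SD, n = 3 each; adjusted p = 0.000266). Markers of other cell types moved as lists too. Adipocyte markers had 1 lower of 10 (6 adjusted over the list alone; list adjusted p = 0.00206, and adjusted p = 0.432 with an estimated correlation). Skeletal muscle markers moved up with none of 12 past the edgeR threshold over all genes (7 adjusted over the list alone; list adjusted p = 0.00334, 0.254 without heart 37, and adjusted p = 0.432 with an estimated correlation), and atrial markers moved down with none of 12 past it (3 adjusted over the list alone; list adjusted p = 0.0321, 0.596 without heart 5, 0.0702 without control vector heart 21, and adjusted p = 0.749 with an estimated correlation). Gdf15 was lower in all 3 hearts, 17.5 ± 3.79 CPM against 40.1 ± 10.4 CPM (SD, n = 3 each), without passing (2.29-fold, adjusted p = 0.151), and it passed in fits of these groups alone (0.0293), without hearts 27 and 37 (0.0367) and with each library a replicate (1.51e-05), where over all alternatives it ran from 1.51e-05 to 0.439. Nppb was 1340.0 ± 179.7 CPM against 1973 ± 232 CPM (SD, n = 3 each), also lower in all 3 hearts (1.47-fold, adjusted p = 0.288). Nppa did not pass (adjusted p = 0.229).

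In knockout ND6 hearts 390 genes passed between the vectors, 270 higher and 120 lower, with 3008 at an unadjusted p under 0.05. Hearts did not overlap in 383 of the 390 and in 3834 of all genes, where chance gives 10%. The count dropped to 41.5% of its size without the heart labelled 8, and to 29.7%, 27.9% and 59.0% without control vector hearts 20, 21 and 22. Cdh5 and Esam did not pass without control vector heart 21 (adjusted p = 0.0592 and 0.0735). With hearts 61 and 91 counted as Ant1 vector hearts 20 genes passed, and Fos, Egr3, Btg2, Zfp36, Dusp1, Cldn5, Esam and Per1 did not, at adjusted p from 0.0653 for Zfp36 to 0.133 for Per1. With both counted as control vector hearts 258 genes passed, Slc25a4 turned to a log2 change of -0.65 (adjusted p = 0.816), and Cdh5, Hspa1a and Rrm2 did not pass (0.0737, 0.0774 and 0.0867). Without hearts 5 and 8, heart 37 alone kept Fos past the threshold at a log2 change of 2.56, while Egr3 (1.08, adjusted p = 0.0598) and Btg2 (0.95, adjusted p = 0.0502) did not pass. A fit of these groups alone ended the Slc25a4 call (0.0542), and libraries a and b alone that of Esam (0.0787). Over all alternatives the adjusted p ran from 9.28e-27 to 0.816 for Slc25a4, from 1.02e-18 to 0.102 for Egr3, from 8.48e-21 to 0.128 for Btg2, from 1.97e-11 to 0.11 for Esam, from 7.43e-13 to 0.0737 for Cdh5 and from 1.07e-21 to 0.0867 for Rrm2.

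In wild type hearts the Ant1 vector left Slc25a4 at 9812 ± 731 CPM (SD, n = 3) against 10392 ± 1347 CPM (SD, n = 4) with the control vector (adjusted p = 0.975). Gdf15 (adjusted p = 0.962), Nppb (0.945) and Nppa (0.927) did not pass. Among the few genes that did were Tat, a liver enzyme of tyrosine breakdown (5.09-fold lower, adjusted p = 0.0417), Id1, an inhibitor of differentiation (1.45-fold lower, adjusted p = 0.0185), Banp (1.80-fold lower), the NAD-consuming enzyme gene Cd38 (1.85-fold higher) and the endothelial receptor gene Nrp1 (1.40-fold higher, adjusted p = 0.0401 for all 3). The albumin gene Alb passed as lower (adjusted p = 0.0482), at 0.0588 to 0.154 CPM in the Ant1 vector hearts, against 159.1, 12.6, 10.8 and 0.248 CPM in control vector hearts 23, 24, 25 and 70.

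Of 18 genes past the threshold 8 were higher and 10 lower, with 1795 at an unadjusted p under 0.05, and DESeq2 called 71 higher and 91 lower. Hearts did not overlap in 17 of the 18 and in 1625 of all genes, where chance gives 5.71%. The count rested on single hearts: 6 genes without Ant1 vector heart 80, 0 without 81 or 83, 2 without control vector heart 24, 0 without 25 and 91 without 70. In the edgeR fits with 0 genes, 1337, 1269 and 1628 had an unadjusted p under 0.05 without hearts 81, 83 and 25. A fit of these groups alone also called 0 genes, with 1643 at an unadjusted p under 0.05. No named gene that passed was kept with each heart left out, at adjusted p up to 0.302 for Banp and Alb, 0.292 for Tat, Cd38 and Nrp1, and 0.11 for Id1. The Xist covariate ended the calls of Tat (0.107), Banp (0.108), Cd38 (0.116), Nrp1 (0.108) and Alb (0.209), and over all alternatives the highest adjusted p was 0.145 for Id1. Endothelial markers (higher), adipocyte markers (lower) and nerve markers (lower) each had a list adjusted p of 0.0179 with no member past the edgeR threshold over all genes, and 2, 8 and 3 adjusted over the list alone. Each list lost its call with 1 heart left out, the endothelial list without 81 (0.106), 83 (0.133) or 23 (0.118), the adipocyte list without 80 (0.0722), 25 (0.0947) or 70 (0.112) and the nerve list without 80 (0.059) or 70 (0.105), and none held with an estimated correlation (0.809, 0.896 and 0.896).

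Under the Ant1 vector, knockout hearts still differed from wild type hearts (4 against 3). Slc25a4 remained lower by a log2 change of -5.60 (adjusted p = 8.13e-06). Nppb was 3.51-fold higher, 1620.9 ± 651.3 CPM (SD, n = 4) against 462 ± 52.6 CPM (SD, n = 3; adjusted p = 0.000309), Acta1 2.87-fold higher, 544.5 ± 201.5 CPM (SD, n = 4) against 189.9 ± 17.5 CPM (SD, n = 3; adjusted p = 0.00271), and Ankrd1 1.80-fold higher (adjusted p = 0.00301), each in all 4 knockout hearts. Gdf15 was 5.80-fold higher (adjusted p = 0.00214), with heart 27 inside the wild type range. Fhl2 was 1.69-fold lower (adjusted p = 0.000159) and Ryr2, the calcium release channel, 1.57-fold lower (adjusted p = 0.00472). Pdhb (1.65-fold), Optn (2.36-fold), Mrpl55 (1.46-fold) and Mrps23 (1.38-fold) were higher. Nppa did not pass (adjusted p = 0.845).

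The knockout hearts kept the wide differences of Arhgap9, Sycp1 and Tmem116 (log2 changes 3.11, 7.35 and 2.73) and of Calr (-7.26) under the Ant1 vector. The receptor subunit gene Grin2c was higher by 2.63 and the cytokine gene Il15 lower at -2.85 (adjusted p = 5.3e-12). Mitochondrial ribosomal genes had 14 higher of 69 (17 adjusted over the list alone; list adjusted p = 6.04e-05, and adjusted p = 0.708 with an estimated correlation), a call lost without wild type heart 81 (adjusted p = 0.069). In all, 1524 genes passed, 827 higher and 697 lower, with 3682 at an unadjusted p under 0.05. Hearts did not overlap in 1406 of the 1524 and in 3073 of all genes, where chance gives 5.71%. Without wild type heart 80 or 83 the count was 894 or 782. With the library table as a covariate 1639 genes passed, 876 of them shared, with log2 changes of 2.24 for Nppb, 2.01 for Acta1, 3.24 for Gdf15 and 1.02 for Ankrd1, against 1.81, 1.52, 2.54 and 0.85 without it. Only knockout heart 20 shared tables with these wild type hearts, so the knockout side of that fit rests on this heart.

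Knockout ND6 hearts labelled Ant1 vector differed from wild type hearts with the Ant1 vector (3 against 3), again with the heart labelled 8 included. Gdf15 was 3.96-fold higher, 17.5 ± 3.79 CPM against 4.39 ± 1.14 CPM (SD, n = 3 each; adjusted p = 0.00882), Nppb 2.90-fold higher (adjusted p = 0.001), Acta1 4.16-fold higher at 789.5 ± 175.4 CPM (SD, n = 3; adjusted p = 0.000172) and Ankrd1 2.38-fold higher (adjusted p = 8.42e-05). Fhl2 was 2.14-fold lower (adjusted p = 3.47e-06), and the atrial genes Myl7 and Sln were both 2.57-fold lower (adjusted p = 0.005 and 0.00286). Heart 5 held 153.9 CPM of Myl7 and 49.2 CPM of Sln, the lowest of the 22 hearts. Immediate early genes had 16 higher and 1 lower of 18 (16 and 1 adjusted over the list alone; list adjusted p = 3.99e-07, and adjusted p = 0.494 with an estimated correlation), including Fos, Egr3 and Btg2 (log2 changes 3.10, 2.89 and 2.10) and Atf3 (2.22, adjusted p = 0.00145). Polrmt was 2.08-fold and Pdhx 1.85-fold higher, and Mrpl55 1.42-fold and Mrps23 (log2 change 0.59) were higher as well. For each of these genes the hearts of both groups did not overlap. Slc25a4 stayed lower at a log2 change of -7.90 and Il15 at -2.81, and Nppa did not pass (adjusted p = 0.181).

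Of 15403 genes 3003 passed, 1661 higher and 1342 lower, with 4934 at an unadjusted p under 0.05. The groups did not overlap in 2844 of the 3003 and in 5246 of all genes, where chance gives 10%. Without wild type heart 80 or 83 the count was 1973 or 1878. Mitochondrial ribosomal genes had 20 higher and 1 lower of 69 (20 and 2 adjusted over the list alone; list adjusted p = 0.0118, and adjusted p = 0.624 with an estimated correlation), a call lost without knockout ND6 heart 5 (0.0845) or wild type heart 81 (0.169), and atrial markers had 4 lower of 12 (4 adjusted over the list alone; list adjusted p = 0.00907, and adjusted p = 0.579 with an estimated correlation), a call lost without heart 5 (0.0675). Without hearts 5 and 8, Fos, Egr3 and Btg2 did not pass (log2 changes 1.15, 0.43 and 0.69, adjusted p = 0.305, 0.44 and 0.105, each the highest over its alternatives), nor did Myl7 (0.0529, its highest, against 6.76e-12 at the lowest). Fos did not pass with hearts 61 and 91 counted as Ant1 vector hearts (0.0518), nor Myl7 in a fit of these groups alone (0.0518). In the fit with the library table as covariate 2185 genes passed, 1422 of them shared, with log2 changes of 3.23 for Gdf15, 2.32 for Nppb, 2.81 for Acta1, 2.96 for Fos, -1.90 for Myl7 and -1.63 for Sln. No knockout ND6 heart shared a table with these wild type hearts. That fit linked them only through the knockout hearts, of which heart 20 alone shared tables with wild type hearts.

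**Figure D3:**
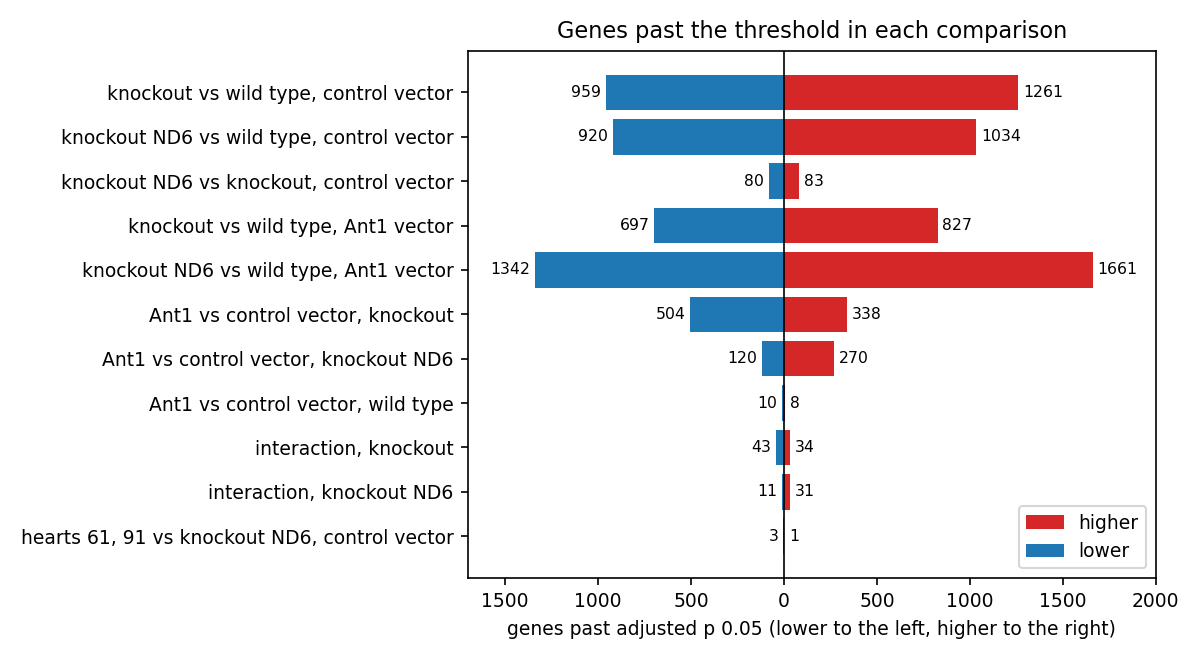
Genes past adjusted p 0.05 in each comparison, with lower genes drawn to the left and higher genes to the right of 0. The bars run from 4 genes in all for hearts 61 and 91 to 3003 in all for knockout ND6 against wild type hearts under the Ant1 vector.

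Whether the vector changed the effect of genotype was tested directly. For Ant1 loss, 77 genes had an effect that differed between vectors, 34 higher and 43 lower under the Ant1 vector, with 2259 at an unadjusted p under 0.05. Slc25a4 differed by 7.75 (log2, adjusted p = 0.00316), Banp by 1.31 (0.0117), Eln by 1.24 (0.0117), Ppp1r10, a subunit of a nuclear phosphatase, by -1.39 (0.00488) and Arhgap32 by -1.42 (0.0117), and these 5 passed under all alternatives. Myh7b differed by 1.44 (0.0136, and 0.0577 without wild type heart 81). The retinol carrier gene Rbp4 (2.51, 0.0396), Mpv17l (-1.36), Gpr22 (-1.30) and Tet1 (-1.30) each lost their call in 9 to 12 of the 14 fits with 1 heart left out, and Rbp4 also with the library table as a covariate (1.03, 0.277). Gdf15 (2.11, adjusted p = 0.145) and Nppb (0.40, adjusted p = 0.675) did not pass. Both did with the library table as a covariate (2.53, adjusted p = 0.000222, and 0.93, adjusted p = 0.00459). Under the Ant1 vector that fit sets wild type hearts against knockout heart 20, the only knockout heart in their tables. The repeat libraries of that heart count there largely as separate units, so the p values can understate the spread between hearts. Over the alternatives the adjusted p ran from 6.08e-05 to 0.277 for Gdf15 and from 0.00459 to 0.916 for Nppb. Fibroblast markers were the only list to pass with each heart left out (1 of 8 higher, 3 adjusted over the list alone; list adjusted p = 0.00536, and adjusted p = 0.103 with an estimated correlation).

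For both defects together 42 genes differed between vectors, 31 higher and 11 lower, with 1615 at an unadjusted p under 0.05, and the heart labelled 8 is again among the hearts. Slc25a4 differed by 6.51 (adjusted p = 0.0134), a call lost without control vector knockout ND6 heart 20 or 21 (0.0576 to 0.0747) and with the library table as a covariate (4.46, 0.105), and turned to -0.57 (0.948) with hearts 61 and 91 as control vector hearts. The immediate early genes Csrnp1 (1.92, adjusted p = 0.00284), Zfp36 (2.24, 0.011), Btg2 (2.16) and Rasd1 (2.52) were higher under the Ant1 vector and Hspa1b lower (-2.54, 0.0287). The platelet and blood cell genes Rgs18 (-2.08), Plek (-1.44) and Pf4 (-1.18, 0.00407) and the defensin-like gene AY761185 (-1.99) had lower differences. From the control to the Ant1 vector, mean Pf4 went from 38.1 to 23.0 CPM in knockout ND6 hearts and from 37.6 to 51.8 CPM in wild type hearts. Rgs18, Plek and AY761185 likewise had lower means in knockout ND6 and higher means in wild type hearts. Csrnp1 and Pf4 passed with each heart left out, Zfp36 did not without control vector heart 21 (0.0526), and the others lost their call in 5 to 12 of 13 such fits. With hearts 61 and 91 counted as Ant1 vector hearts none of these 9 genes passed, from 0.0534 for Hspa1b and 0.332 for Csrnp1 to 0.628 for Btg2, and with both as control vector hearts Hspa1b did not (0.356). Libraries a and b alone ended the calls of Rasd1, Btg2, Rgs18, Plek, Pf4 and AY761185 (0.0526 to 0.453). The library table as a covariate ended the calls of Rgs18 (0.0802), Plek (0.0529), Pf4 (0.257) and AY761185 (0.726). Over all alternatives the adjusted p ran from 6.22e-18 to 0.332 for Csrnp1, from 1.1e-14 to 0.367 for Zfp36 and from 3.11e-13 to 0.356 for Hspa1b. The immediate early list passed (4 of 18 higher, 13 adjusted over the list alone; list adjusted p = 5.64e-11, and adjusted p = 0.538 with an estimated correlation) and so did the cell cycle list, lower (1 of 21, 4 adjusted over the list alone; list adjusted p = 0.000126, and adjusted p = 0.576 with an estimated correlation). Gdf15 (-1.30, adjusted p = 0.506) and Nppb (-0.49, adjusted p = 0.704) did not pass.

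Each heart moved the counts of differing effects. For Ant1 loss they were 28 and 32 without Ant1 vector knockout hearts 21 and 22, 82 higher with 90 lower without heart 27, and 34, 19 and 24 without control vector knockout hearts 35, 36 and 38. They were 31, 15 and 22 without wild type hearts 80, 81 and 83, and 38, 46 and 29 without wild type hearts 24, 25 and 70. For both defects they were 94, 16 and 13 without hearts 37, 5 and 8, and 11, 9 and 10 without control vector knockout ND6 hearts 20, 21 and 22. They were 13, 13 and 10 without wild type hearts 80, 81 and 83, and 25, 13 and 24 without wild type hearts 24, 25 and 70. With the library table as a covariate 493 genes passed for Ant1 loss, 48 of them shared, and for both defects 4.69 times as many as without it, 24 of them shared. Under the Ant1 vector both fits reach the wild type hearts through knockout heart 20 alone.

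Gene by gene, knockout effects under the control vector mostly kept their direction under the Ant1 vector. Of the 2220 genes changed by Ant1 loss 82.6% had the same sign and 69.4% the same sign with a smaller effect, and 464 rose under both vectors where 67.7 were expected by chance, with 210 lower under both (43.4 expected) and 14 opposite. Chosen from the Ant1 vector instead, 62.7% of 1524 genes had the same sign and a smaller effect under the control vector. Of the 1954 genes changed by both defects 92.2% had the same sign and 56.3% the same sign with a smaller effect under the Ant1 vector, and in the reverse choice 76.8% of 3003 did. Because genes picked for a large effect shrink in any other set of hearts, the shares in both directions belong together.

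Hearts 61 and 91, labelled control vector, were compared with the 3 control vector knockout ND6 hearts as a group of their own. Slc25a4 was 160.2 ± 12.6 CPM (SD, n = 2) against 0.478 ± 0.331 CPM (SD, n = 3; log2 change 8.38, adjusted p = 0.000339), with 7.66 when the library table is a covariate. Rrm2 (3.43-fold lower, adjusted p = 0.0022), Hspa1b (6.53-fold lower, adjusted p = 0.00849) and the replication gene Mcm5 (2.28-fold lower, adjusted p = 0.0229) were lower in both hearts, and these 3 were chosen after their values were seen. The 4 genes were all that passed, with 815 at an unadjusted p under 0.05 and 9 past the threshold in DESeq2, and hearts did not overlap in all 4 and in 4234 of all genes, where chance gives 20%. Without heart 61 or 91 only 1 gene passed, and without control vector heart 20 there were 2. Rrm2 lost its call without 61 or 91 (adjusted p from 0.144 to 0.221), Hspa1b without 61, 91 or 20 (0.0565 to 0.668) and Mcm5 without the same hearts (0.23 to 1). With the library table as a covariate 40 genes passed, 3 of them shared, with log2 changes of -1.76 for Rrm2, -2.33 for Hspa1b and -1.05 for Mcm5 (adjusted p = 0.279). Gdf15 stood at 44.2 CPM in heart 61 and 19.8 CPM in heart 91.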

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

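The tests of the immediate early genes below were chosen only after the result was seen, while those of Gdf15 were written before. The effect of Ant1 loss differed between the vector groups (the test of the interaction) for Slc25a4 (log2 difference 7.75), Rbp4 (2.51), Myh7b (1.44), Banp (1.31) and Eln (1.24), which were higher under the Ant1 vector, and for Gpr22 (-1.30), Tet1 (-1.30), Mpv17l (-1.36), Ppp1r10 (-1.39) and Arhgap32 (-1.42). Of these Rbp4, Mpv17l, Gpr22 and Tet1 lost their call in most fits with 1 heart left out, Myh7b in 1 of them, and Rbp4 also with the library table as a covariate. For both defects together the same test picked out Slc25a4 (6.51), Rasd1 (2.52), Zfp36 (2.24), Btg2 (2.16) and Csrnp1 (1.92), and Pf4 (-1.18), Plek (-1.44), AY761185 (-1.99), Rgs18 (-2.08) and Hspa1b (-2.54), of which only Csrnp1 and Pf4 kept their call with each heart left out, and Pf4 lost it with the library table as a covariate. Single hearts apart from the other 3 of their group by Dixon's test were wild type heart 23 for Alb (159.1 CPM, nearest 12.6), wild type heart 70 for Mrps18b (68.3 CPM, nearest 86) and Ppp1r10 (47.8 CPM, nearest 54.6), and Ant1 vector knockout hearts 27 for Arhgap32 (21.3 CPM, nearest 15.8) and 20 for Ppp1r10 (30.1 CPM, nearest 49). Chance alone sets apart about 1 in 20 groups, and 5 of the groups of 4 hearts tested were, no more than chance would give.

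Immediate early genes were high in the knockout ND6 hearts labelled Ant1 vector. The amount of vector-derived Slc25a4 transcript is argued against as the cause: knockout hearts with the Ant1 vector held more of it, yet their immediate early genes had a median log2 change of 0.15 (spread 0.14) against 2.02 (spread 0.32) in the knockout ND6 hearts, and the heart labelled 8 had almost none. Spread here is the SD of the genes around their median divided by the root of the list size. It takes genes, not hearts, as units, and single genes varied more widely. A difference between library tables is argued against too, since the lower of hearts 5 and 8 exceeded the higher of Ant1 vector knockout hearts 21 and 22 in the same tables by 2.07 in mean log2 CPM. Time or handling at collection could raise such genes within minutes, and 0 of the samples have a label for it, so it stays open. Against an effect of genotype and vector transcript together stand knockout ND6 hearts 61 and 91, with 169.1 and 151.3 CPM of Slc25a4 but immediate early means of 3.39 and 3.57, near the control vector knockout ND6 hearts (3.24 to 3.52), though the vector label of both is unexplained. Without hearts 5 and 8 the list kept its call between vectors in knockout ND6 hearts on heart 37 alone (adjusted p = 0.000337), and not in the interaction (0.0543).

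Gdf15 was high in Ant1 vector knockout hearts 20, 21 and 22 but not in heart 27. The control vector knockout ND6 hearts, with 29.7 to 50.4 CPM of Gdf15, have the same title numbers 20, 21 and 22. On a scale of the genes that differ between control vector knockout (0) and knockout ND6 hearts (1), the lowest of hearts 20, 21 and 22 lay at 0.58 and heart 27 at 0.36, all above the control vector knockout hearts (-0.06 to 0.07). Wild type hearts, which carry no ND6 change, lay between 0.33 and 0.53, so the scale does not separate the genotypes, and the tests are void. The rule that made them void was added after the values were seen, and by the rule written before, both would have read as met. Neither a wrong genotype label of hearts 20, 21 and 22 nor an effect of the vector can be told apart here, and the age of the hearts stays open and untested.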

How the results depend on the processing

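Chosen after the data were seen were the fits without hearts 27 and 37, without library 27a, without hearts 5 and 8, and without chromosome 8 from 30 to 95 Mb. Groups of 2 to 4 hearts, vector tied to library table, unknown ages and the unexplained labels of heart 8, hearts 61 and 91 and libraries 80a and 80b limit all comparisons. No paired analysis was possible because the groups compared share no heart numbers. Without hearts 5 and 8 the group keeps the lone heart 37, which is assumed to vary like the other groups. Counts below are given as multiples of the count in the report, for knockout against wild type (A), knockout ND6 against wild type (B) and knockout ND6 against knockout (C) under the control vector, for the vector in knockout (D), knockout ND6 (E) and wild type hearts (F), for A and B under the Ant1 vector (G and H), for the interactions of A and B with the vector (J and K) and for hearts 61 and 91 (L). The cause of the shifts was not tested.

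With each library a replicate the multiples were 2.5 (A), 2.48 (B), 18.6 (C), 5.9 (D), 11.9 (E), 88.4 (F), 2.74 (G), 1.86 (H), 33.1 (J), 39.9 (K) and 126.2 (L). With libraries a and b only they were 0.66 (A), 0.62 (C), 0.52 (E), 0.39 (F), 0.59 (G), 0.63 (H), 0.13 (J) and 0.29 (K). Without hearts 70, 22, 27 and 37 they were 2.31 (C), 2.3 (D), 2.49 (E), 21.3 (F), 1.6 (G), 5.86 (J) and 2.24 (K), and without hearts 27 and 37 alone 1.77 (D), 1.57 (E), 4.91 (J) and 3.26 (K). With only the compared groups in the fit they were 5.17 (C), 0.28 (D), 0.47 (E), 0 (F), 0.57 (G), 0.64 (H) and 3.5 (L). In DESeq2 they were 2.96 (C), 1.68 (D), 2.23 (E), 9 (F), 4.75 (J), 4.12 (K) and 2.25 (L). With single libraries and the table covariate they were 11 (C), 6.4 (J), 4.69 (K) and 10 (L). With hearts 61 and 91 in the control vector group they were 1.53 (B), 3.86 (C), 0.66 (E) and 0.48 (K), and in the Ant1 vector group 0.05 (E) and 0.05 (K). Without the low-count filter they were 0.61 (D), 1.61 (F) and 0.58 (J), with the Xist covariate 0.44 (F), 1.58 (J) and 1.88 (K), without hearts 5 and 8 of the Ant1 vector group 2.12 (E) and 4.52 (K), and without chromosome 8 from 30 to 95 Mb 0.5 (L).

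Leaving out 1 heart at a time gave multiples from 0.62 to 0.89 (A), 0.51 to 0.87 (B), 0.28 to 0.48 (C), 0.26 to 1.25 (D), 0.28 to 0.93 (E), 0 to 5.06 (F), 0.51 to 1.08 (G), 0.63 to 0.86 (H), 0.19 to 2.23 (J), 0.21 to 2.24 (K) and 0.25 to 1.25 (L). The number of lists past the threshold ran from 6 to 13 (A), 4 to 10 (B), 4 to 8 (C), 6 to 8 (D), 7 to 13 (E), 2 to 4 (F), 0 to 7 (G), 2 to 8 (H), 1 to 8 (J) and 2 to 7 (K). Of 51 list calls 25 were kept with each heart left out, 51 with a prior count of 0.5, 19 with fry and 3 with an estimated correlation. With the estimated correlation gene list tests passed for 1 list each in A, B and C and 0 in D, E, F, G, H, J and K. With fry they passed for 1 (C), 3 (D), 0 (F), 14 (H), 1 (J) and 0 (K), and without hearts 5 and 8 of the Ant1 vector group for 7 (H). The share of genes with the same sign and a smaller effect under the Ant1 vector ran from 66.5% to 73.8% for Ant1 loss and from 54.5% to 61.3% for both defects, and was 62.7% and 76.8% under reverse selection.

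With hearts 61 and 91 in the control vector group Slc25a4 turned direction: its log2 change became 6.00 (adjusted p = 0.0496) in C, -0.65 (0.816) in E and -0.57 (0.948) in K. For the named genes past the threshold 2926 of 3166 values kept the call and 238 no longer passed (mostly with 1 heart left out). For those not past it 18 of 407 values newly passed. Of the named genes past the threshold, 80.1% passed with each heart left out.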

Other observations

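The tests on chromosome 8 were chosen only after the result was seen, while the regrouping of hearts was planned. Knockout heart 27 stood apart from the other Ant1 vector knockout hearts: it held 710.6 CPM of Nppb and 5.29 CPM of Gdf15, against 1675.8 to 2242 CPM and 24.7 to 42.9 CPM in hearts 20, 21 and 22, with Slc25a4 at 174.3 CPM against 197.4 to 241.4 CPM. Between its tables its libraries had squared differences of 19 to 53.4 times counting noise, and within a table library 27a differed by 35.7 to 38.5 times from the other 3 and the rest by up to 22.6 times. For knockout ND6 heart 37 these were 9.78 to 29.9 times between tables and up to 10.6 times within. First libraries of different hearts of a group had a median of 5.03, so reading either set as repeat libraries of 1 heart is doubtful. Pairs from some other hearts exceeded that median too, up to 7.69 in control vector knockout heart 36 and 11.8 in wild type heart 70. The doubt is thus not confined to hearts 27 and 37. Knockout ND6 heart 5 was low in atrial transcripts, with 1072.2 CPM of Nppa besides the low Myl7 and Sln, and the cause was not tested. Wild type heart 70 had a mean log2 CPM of 4.17 over the immediate early genes, where hearts 23, 24 and 25 had 2.97 to 3.14. Alb, a liver transcript, fell from 159.1 CPM in heart 23 to 0.248 CPM in heart 70.

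Libraries 80a and 80b, whose vector labels and titles differ, looked like wild type hearts, with 10119.9 and 10731.8 CPM of Slc25a4, 499.8 and 500.6 CPM of Calr, 408.4 and 411.8 CPM of Nppb, and 0 and 0.248 CPM of Sycp1. Wild type hearts with either vector held similar Slc25a4, so these values do not tell which vector was given.

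Near-complete loss of amplicon counts marked 4 genes of chromosome 8, which also carries Slc25a4, in knockout hearts under both vectors: Calr, Pdgfrl, Ubxn8 and Zswim4. Ucp1 on the same chromosome missed a 16-fold change for knockout ND6 hearts with the control vector (log2 change -3.44) and for knockout hearts with the Ant1 vector (-2.81), where the wild type hearts held only 1.87 to 6.18 CPM of it, against 6.55 to 35.1 CPM with the control vector. Library tables are argued against as the cause, since the 4 genes kept a median log2 change of -6.44 with the table as a covariate. An effect of Ant1 loss that does not depend on position is argued against by 4 such genes among 535 on chromosome 8 and 0 among 9059 elsewhere (Fisher's exact test, two-sided, p = 9.57e-06). A strain variant carried with the knockout allele, over which the amplicons read poorly, may have removed these 4, and stays open because no sequence was examined here. Other named genes lie between Ubxn8 and Calr, among them Gdf15 (70629393 to 70632470) and Ndufb7 (83566758 to 83571623). Whether such a variant bears on their counts was not tested.

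A chance division of the hearts is less likely, though not excluded, where other splits of the same hearts were many and gave fewer genes. The lowest share that 35 splits can reach is 1 in 35. Only 1 of 35 splits, the real one, gave as many genes for knockout against wild type (2220, highest other 601), for knockout ND6 against wild type (1954, highest other 600), for the vector in knockout hearts (842, highest other 586) and for knockout against wild type under the Ant1 vector (1524, highest other 843). The 586 came with heart 27 among the control vector hearts, and the 843 with heart 27 among the wild type hearts. With 10 splits there are too few to judge chance. The values were 390 against 2 for the vector in knockout ND6 hearts and 3003 against 12 for knockout ND6 against wild type under the Ant1 vector. For knockout ND6 against knockout no other split called a gene (0). For the vector in wild type hearts 2 of 35 splits gave as many, and the highest, 76 against 18, set hearts 23, 24 and 25, whose libraries share their tables, against heart 70 with the Ant1 vector hearts, whose libraries sit in others. Whether the tables cause this was not tested. For the interactions 2 of 50 drawn splits gave as many. The highest others, 532 against 77 for Ant1 loss and 500 against 42 for both defects, each kept the real genotype groups under 1 vector and mixed them under the other, so they recover the genotype effect itself and say little about chance.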
